A study of Homo sapiens with 18 samples.

How the data were processed

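Total RNA from the colorectal cancer cell lines HCT116, LS174T and SW480 was measured on Illumina HT-12 expression BeadChips, which read each transcript with 50-base bead-bound probes in a single colour. Per the labels, cells were given calcitriol (the hormonally active form of vitamin D) at 50 nM or its ethanol vehicle for 16 h, in medium with charcoal-treated serum for the treatments. RNA was amplified and labelled as biotinylated cRNA, per the labels' protocols. The 18 arrays fall into 6 groups of 3, each array being placed by the cell line and treatment in its labels. The labels number the replicates but do not say that they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

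The authors deposited a table of probe intensity on a linear scale, not normalized, with a detection p-value beside each intensity, per the file headers. It lists 47323 probes with an identifier and 887 rows without one, which were left out of normalization and of every gene test. The software that summarised the bead intensities is not given in the sources used here, and the lowest intensity in the table was 90.6. The authors also deposited a table of log2 values for the same arrays, whose processing the labels do not describe beyond naming limma in the submitters' processing notes, without a version. Each of the 18 raw columns correlated best with its own deposited array. The log2 values computed here differed from the deposited ones by a median of 0.0033 and at most 0.205, with a correlation of at least 0.999998 on every array, which settles the scale of the deposited table as background-corrected, quantile-normalized log2 intensity. The deposited column medians all lay at 5.19.

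From the raw intensities, background was corrected and arrays were quantile-normalized with the neqc method of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values and an offset of 16. Probes were kept if their detection p was under 0.05 on at least 3 of the 18 arrays, which left 25586. Of all probes, 30113 had 1 gene symbol in the platform annotation, 8 had several and 17202 were not listed there. Symbols of 30074 probes were updated through their Entrez identifiers to the RefSeq gene table of assembly GRCh38.p14. The files name no genome build, so that table served for names and gene order and no coordinates are given. Each gene was represented by its probe with the highest mean over all arrays, giving 13712 genes. Of these, 3747 had several probes that passed the filter.

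Group means were fitted to all 18 arrays with lmFit and eBayes of limma, so that all groups shared an estimate of the spread, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Contrasts were calcitriol minus ethanol in each line, the mean of these 3 differences, a moderated F-test of whether the 3 responses differed, and a moderated F-test of differences among the lines in ethanol. Changes are differences of mean normalized log2 intensity with the standard error from the moderated fit (SE). The offset shrinks changes of dim probes. Where a probe was not detected on any array of a group, its fold is a lower bound. The bound sets the mean of the brighter group against, per array, the higher of the probe's own value and the lowest value among detected probes. Levels of different probes were not set against each other.

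Gene lists fixed before the data were examined were tested with camera of limma at its preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. Of 417 listed genes, 329 were measured, and 21 of the 22 lists had the 5 tested genes that camera was asked for. The lists held canonical vitamin D receptor targets, the receptor with its partners and vitamin D metabolism, epithelial adhesion, mesenchymal transition, Wnt/beta-catenin targets, proliferation, growth arrest, enterocyte, goblet and intestinal stem cell markers, MYC targets, interferon response, NF-kB and inflammatory genes, endoplasmic reticulum and amino acid stress, cholesterol synthesis, NRF2 redox genes, ERK feedback and ligands, hypoxia and glycolysis, xenobiotic metabolism and transport, apoptosis regulators, and markers of fibroblasts and of leukocytes and endothelium as cell types that could have been mixed in. Overlaps of calls between lines were set against n1 × n2 / N and tested with a one-sided Fisher's exact test, adjusted over the pairs and directions.

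Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls of each comparison among genes past the threshold whose calcitriol and ethanol arrays did not overlap (for the average, with the same sign in all lines), the 10 smallest F-test p-values for differing responses, up to 4 members of a list where the list or a member passed, and CDH1, CYP24A1, VDR, RXRA, MYC, TRPV6 and CDKN1A whatever their values. Genes outside it are said to have been chosen after their values were seen. Members of a list counted as past the threshold may also be named with that count.

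The fit was tested on simulated arrays of 13712 genes, 50 of them changed by each of several known folds. For the LS174T comparison it recovered 90% of the genes changed 2-fold, 70% of those changed 1.5-fold and 22% of those changed 1.25-fold. For the HCT116 comparison the shares were 78%, 66% and 10%. A gene had the same simulated spread in every line, so the gap between the comparisons reflects the genes and noise drawn. The simulated HCT116 comparison gave 133 calls and the real one 10. Fewer calls make the adjusted threshold stricter, so these shares may be too high for the real HCT116 comparison. Alternatives tried were the deposited log2 values, no background correction, median scaling in place of quantile normalization, an offset of 50, no filter, a stricter filter, the mean of a gene's probes, every probe on its own, eBayes with trend and robust settings, array weights, the replicate number as a block, a log2 change of at least 1, only the arrays of the line compared, and each array left out in turn. The BeadChip as a block was not run, since the files do not say which chip held which array. The log2 mean raw intensity of each array as a covariate was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.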

Results

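Gene expression was measured on 18 BeadChip arrays from 3 human colorectal cancer cell lines, HCT116, LS174T and SW480, each with 3 arrays after ethanol vehicle and 3 after 50 nM calcitriol for 16 h. Between 19295 and 21028 probes were detected per array, which was 40.8% to 44.4% of the probes. Replicates correlated at 0.992 to 0.994, and the median SD between replicates was 0.12 to 0.13 log2 units in every group. The arrays differed mainly by cell line, with 52.5% and 40.5% of the variance on the first and second principal components. In each line n = 3 per group, and replicates are not stated to be separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

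The lines differed widely before treatment, including in the receptor through which calcitriol acts. VDR, which encodes the vitamin D receptor, had a mean level of 8.27 ± 0.17 (SD, n = 3) log2 units in LS174T, 6.98 ± 0.34 in SW480 and 5.50 ± 0.20 in HCT116 in ethanol. It was higher in LS174T than in HCT116 by 2.77 log2 units (adjusted p = 1.16e-09) and higher in SW480 than in HCT116 by 1.48 (adjusted p = 2.21e-06). CYP24A1, the mitochondrial enzyme that inactivates calcitriol, went the other way, at 11.16 ± 0.07 in HCT116 and 9.16 ± 0.15 in SW480 in ethanol while no LS174T ethanol array detected it. CDH1, which encodes the adhesion protein E-cadherin, was highest in HCT116 at 10.24 ± 0.04, against 8.42 ± 0.14 in LS174T and 7.77 ± 0.11 in SW480. In all, 10933 of 13712 genes (79.7%) differed among the lines in ethanol by the moderated F-test.

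The series was designed around the induction of CDH1 by calcitriol, which its submitters also followed by quantitative PCR in further lines not analysed here. CDH1 rose by 1.23 ± 0.09 (SE) log2 units in SW480, a 2.34-fold change (adjusted p = 2.43e-06), and by 0.78 ± 0.09 in LS174T, a 1.72-fold change (adjusted p = 4.83e-05). In HCT116 the difference was 0.40 ± 0.09 and did not pass the threshold over all genes (adjusted p = 0.157), whereas adjusted over the 3 lines alone it did (adjusted p = 0.000574). The last value equals its unadjusted p, which was the largest of the 3 lines. All 3 calcitriol arrays lay above all 3 ethanol arrays in each line. Calcitriol and ethanol arrays did not overlap, in either direction, for 2132 of 13712 genes in HCT116, 3220 in LS174T and 3026 in SW480. Averaged over the lines CDH1 rose by 0.80 ± 0.05 (adjusted p = 1.98e-07). Its responses differed among the lines (adjusted p = 0.00422), with SW480 above HCT116 by 0.83 (adjusted p = 0.0059), while the difference of 0.45 between SW480 and LS174T did not pass (adjusted p = 0.0808). The gene was read by 1 probe. Without background correction the HCT116 difference of 0.37 passed the threshold (adjusted p = 0.0252, in a range of 0.0252 to 0.461 over the alternatives).

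**Figure D1:**
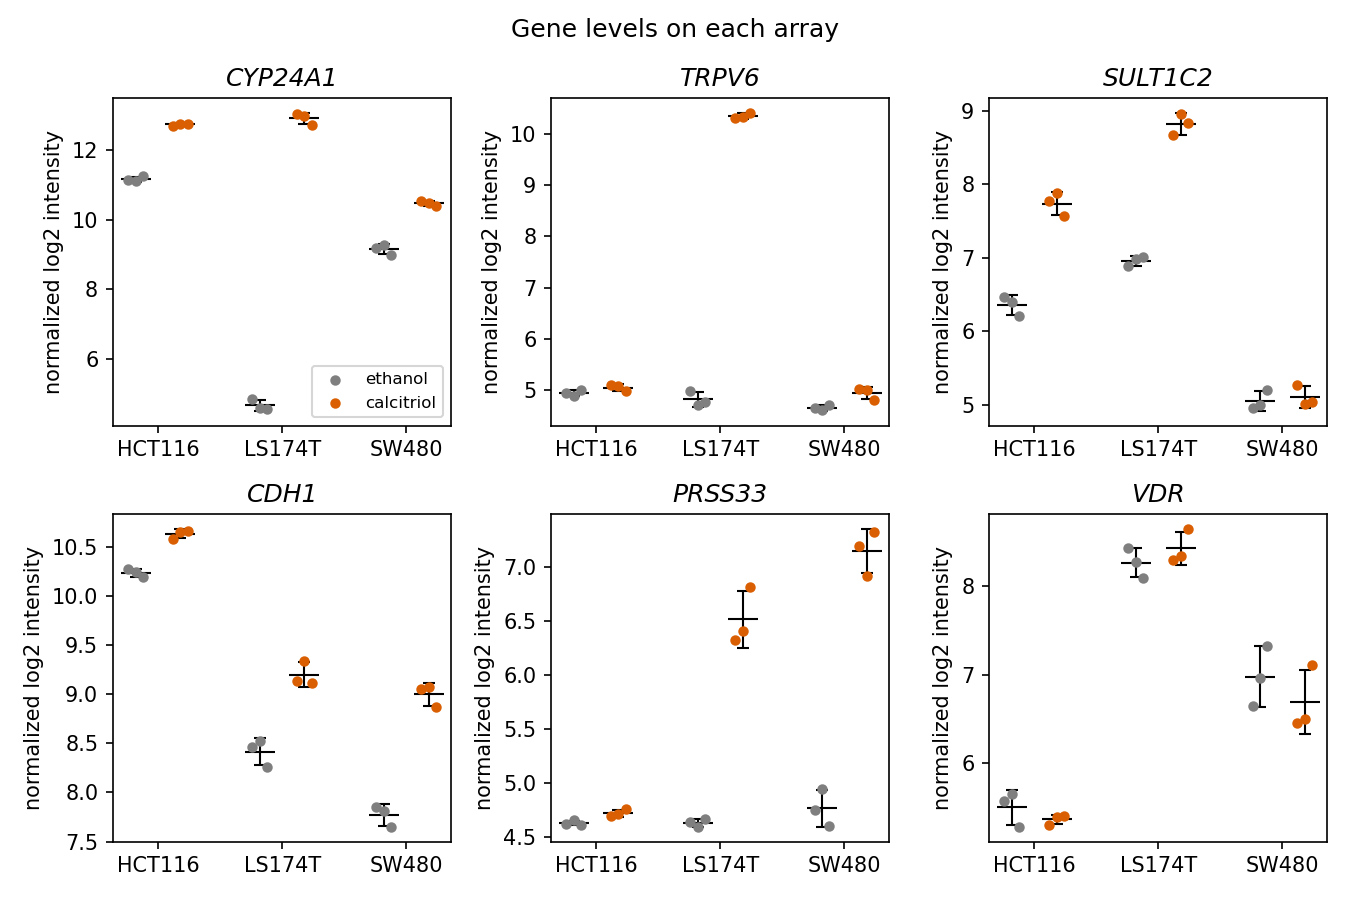
Normalized log2 intensity of 6 genes on each of the 18 arrays, by cell line, with ethanol arrays in grey and calcitriol arrays in orange. Horizontal marks are means and bars are SD (n = 3); TRPV6 reached 10.35 in LS174T with calcitriol and was not detected in the other lines, while VDR showed no change past the threshold.

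Among 16 measured canonical vitamin D receptor targets, 11 rose and 1 fell in LS174T, 2 rose in HCT116, and 1 rose and 1 fell in SW480. Adjusted over the list alone, 13 rose and 1 fell in LS174T, 6 rose in HCT116, and 6 rose and 1 fell in SW480. The 6 in SW480 include TRPV6, which differed by 0.28 there although no SW480 array detected it. CYP24A1 was the only gene higher past the threshold in all 3 lines. It rose by 1.57 ± 0.10 in HCT116 (adjusted p = 9.5e-07), by 1.31 ± 0.10 in SW480 (adjusted p = 2.44e-06) and by at least 175-fold in LS174T (adjusted p = 8.61e-18), where it went from undetected to 12.90 ± 0.16. TRPV6, an apical calcium channel of the intestine, rose at least 29.8-fold in LS174T (adjusted p = 1.47e-16). It was detected on no HCT116 or SW480 array. SULT1C2, a sulfotransferase, rose by 1.86 ± 0.11 in LS174T (adjusted p = 2.04e-08) and by 1.38 ± 0.11 in HCT116 (adjusted p = 1.23e-05), and differed by 0.05 in SW480 (adjusted p = 0.871). SERPINB1, a protease inhibitor, and EFL1, a ribosome assembly factor, rose by 1.31 and 1.24 in LS174T and differed by 0.46 and 0.56 in HCT116 (adjusted p = 0.0851 for each). BCL6, a transcriptional repressor, fell by 0.52 in LS174T (adjusted p = 0.00746) and by 0.90 in SW480 (adjusted p = 0.00036). As a set the targets shifted upward in LS174T (camera adjusted p = 2.66e-27), in HCT116 (3.99e-08) and in SW480 (0.018). The shifts in LS174T and HCT116 held (adjusted p = 1.49e-05 and 0.00578 with an estimated correlation), and that in SW480 did not (adjusted p = 0.335 with an estimated correlation).

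**Figure D2:**
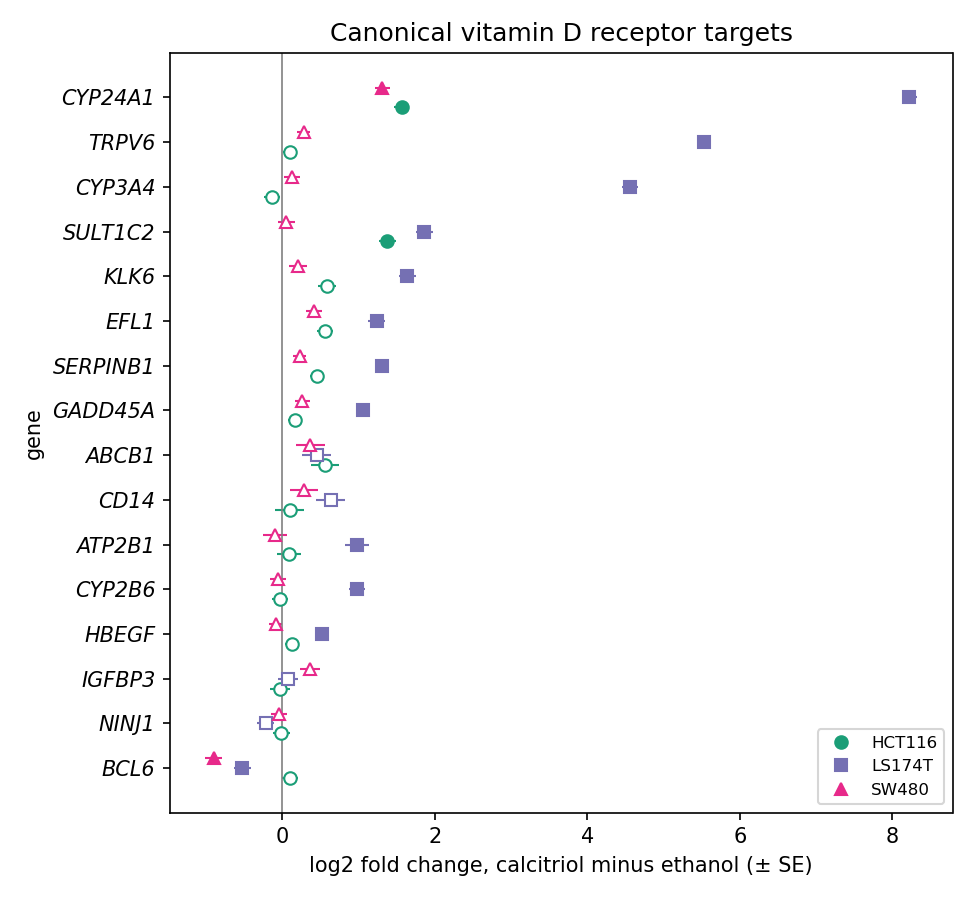
Log2 fold change, calcitriol minus ethanol, of the 16 measured canonical vitamin D receptor targets in HCT116 (circles), LS174T (squares) and SW480 (triangles), with bars of 1 SE and filled symbols for genes past an adjusted p of 0.05. LS174T lies farthest to the right for CYP24A1 at 8.22 and TRPV6 at 5.53, values whose ethanol side was not detected, and BCL6 lies to the left of 0 in LS174T and SW480.

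In HCT116 calcitriol raised 7 genes and lowered 3, of which 4 changed at least 2-fold. After CYP24A1 and SULT1C2, the largest rises were those of PADI3, which converts protein arginine to citrulline (1.07 ± 0.13, adjusted p = 0.00159), and of GEM, a small GTP-binding protein (0.81 ± 0.12, adjusted p = 0.0135). ERV3-1, the collagen gene COL9A2 and MMP7, a matrix protease and Wnt target, rose by 0.81, 0.55 and 0.49. POLR1G, a subunit of RNA polymerase I, fell by 1.03 ± 0.16 (adjusted p = 0.0266), FIRRM fell by 0.48 ± 0.08 (adjusted p = 0.0365) and ANGPT1, a ligand of an endothelial receptor, fell at least 1.57-fold (adjusted p = 0.0385). A dimmer second probe of ANGPT1 went the other way, at 0.39.

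Proliferation genes lay lower in HCT116 with calcitriol as a set. Of 27 measured, 25 had a negative difference, among them MKI67 at -0.35, RRM2 at -0.32, MCM2 at -0.30 and CDC20 at -0.28, and the median was -0.15. None passed over all genes with limma (6 at an unadjusted p under 0.05), and 3 were lower adjusted over the list alone. The set's shift passed (camera adjusted p = 4.42e-08) and held with an estimated correlation (adjusted p = 0.017 with an estimated correlation). MYC targets, genes of ribosome and nucleolus assembly, also lay lower, with a median of -0.19 (camera adjusted p = 0.000186; adjusted p = 0.178 with an estimated correlation). Among them UTP20 differed by -0.68, PPAN by -0.57, BOP1 by -0.30 and NOLC1 by -0.27, none of them past the threshold (adjusted p from 0.225 to 0.325), and UTP20 was not detected with calcitriol. No MYC target passed with limma (6 at an unadjusted p under 0.05), and 3 were lower adjusted over the list alone. Leaving out 1 array at a time ended the calls of COL9A2, MMP7, POLR1G, ANGPT1 and FIRRM in 5 of 6 fits and of ERV3-1 in 4 (adjusted p up to 0.172). GEM did not pass without ethanol replicate 3 or calcitriol replicate 2 (adjusted p up to 0.0828). With only the 6 HCT116 arrays 3 genes passed. The count was 4 without ethanol replicate 3, and 5, 3 and 6 without calcitriol replicates 1, 2 and 3. Under median scaling 8 genes passed, 8 of them higher. Without background correction 12 genes were higher and 11 lower, with trend and robust settings 14 and 10, and with array brightness as a covariate, chosen after the data were seen, 5 genes passed.

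In LS174T calcitriol raised 385 genes and lowered 444, and 118 of these changed at least 2-fold, 82 upward and 36 downward. The largest rises after CYP24A1 and TRPV6 included several drug- and steroid-handling enzymes. CYP3A4, the main drug-oxidizing cytochrome of liver and intestine, rose at least 14.2-fold (adjusted p = 2.99e-14) and its relative CYP3A5 rose by 4.02 ± 0.18 (adjusted p = 6.71e-10). CYP4F3, which oxidizes leukotrienes, rose by 3.37 ± 0.16 (adjusted p = 6.71e-10), and HSD3B1, a steroid dehydrogenase, at least 7.08-fold (adjusted p = 4.28e-09). PADI3 rose by 3.95 ± 0.13 (adjusted p = 5.48e-12), CA2, a carbonic anhydrase of absorptive cells, at least 5.86-fold (adjusted p = 1.36e-12), FOS, a subunit of the AP-1 transcription factor, by 3.14 ± 0.13 (adjusted p = 2.69e-10), and PRR5L, a partner of mTOR complexes, at least 5.71-fold (adjusted p = 4.95e-10).

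Of 13 measured genes of xenobiotic metabolism and transport, 5 rose in LS174T (6 adjusted over the list alone), and the set shifted upward (camera adjusted p = 1.05e-05; adjusted p = 0.0174 with an estimated correlation). UGT1A1, which glucuronidates bilirubin, rose by 1.81 ± 0.09 (adjusted p = 1.82e-09) and CYP2B6 at least 1.47-fold (adjusted p = 2.25e-05). The transcripts of the UGT1A locus share exons and those of the CYP3A genes are similar, so probes may not separate the members. The largest falls included 2 glucuronosyltransferases of another subfamily, UGT2B10 at least 2.15-fold (adjusted p = 3.62e-07) and UGT2B11 by 1.48 ± 0.21 (adjusted p = 0.000303). UGT2B15 of the xenobiotic list also fell and was not detected with calcitriol (adjusted p = 2.49e-05). GPR15LG, a colonic chemoattractant, fell by 2.28 ± 0.14 (adjusted p = 2.96e-08), C2CD4A by 1.69 ± 0.09 (adjusted p = 7.65e-09), PTGDR, a prostaglandin D2 receptor, by 1.67 ± 0.10 (adjusted p = 2.83e-08), and SLC3A1, a subunit of a cystine transporter, at least 2.42-fold (adjusted p = 3.49e-07). ODAM, MT4, SBSPON and GAS7 fell by 1.65, 1.58, 1.55 and 1.51.

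Markers of intestinal cell types moved in LS174T in both directions. Goblet markers lay lower as a set (camera adjusted p = 0.00388; adjusted p = 0.123 with an estimated correlation), with 4 of 12 lower (7 lower and 1 higher adjusted over the list alone). ATOH1, the transcription factor that specifies secretory cells, fell by 0.96 ± 0.15 (adjusted p = 0.000837), RETNLB by 1.14 ± 0.20 (adjusted p = 0.00235), FCGBP by 0.59 and SPINK4 by 0.40. A second probe of RETNLB had a difference of 0.27. Among 14 enterocyte markers CA2 rose and MYO1A, a brush border myosin, fell and was not detected with calcitriol (adjusted p = 1.31e-06). Among 16 stem cell markers LRIG1, a membrane protein that restrains growth factor signalling, rose by 0.60, LGR5 rose by 0.62, RGMB fell by 0.77, and AXIN2 and CD44 fell by 0.35 and 0.42. Of 22 Wnt/beta-catenin targets 7 fell and LGR5 rose, with 7 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0389; adjusted p = 0.206 with an estimated correlation). NKD1, a Wnt feedback inhibitor, fell by 1.16 ± 0.16 (adjusted p = 0.00019), SP5 at least 1.97-fold (adjusted p = 0.00614), RNF43, which removes Wnt receptors from the surface, by 0.51 and BMP4 by 0.49. Another probe of CD44 had a difference of 0.03.

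In the ERK feedback and ligand list, 6 of 20 members rose and 2 fell in LS174T (8 and 4 adjusted over the list alone; camera adjusted p = 0.0381; adjusted p = 0.123 with an estimated correlation). Beside FOS, the immediate early gene EGR1 rose by 0.71 ± 0.09 (adjusted p = 0.000112), PHLDA1 by 0.93 ± 0.10 (adjusted p = 1.53e-05), and EPHA4, an ephrin receptor, fell by 1.21 ± 0.14 (adjusted p = 2.29e-05). MYC targets shifted upward (camera adjusted p = 0.0159; adjusted p = 0.255 with an estimated correlation), where NOP56 rose by 0.36 and its other probes differed by 0.06 and 0.08. Of 20 adhesion genes CDH1, CLDN2, a pore-forming claudin (1.61 ± 0.13, adjusted p = 6.25e-07), and PKP2 rose, while DSP, a desmosome protein (-0.60 ± 0.08, adjusted p = 0.000158), and CGN fell. Of 27 proliferation genes CDC6 and RRM2 rose by 0.65 and 0.39 and CENPF fell by 0.41. Of 14 growth arrest genes GADD45A rose by 1.06 ± 0.09 (adjusted p = 1.73e-06) and TOB1 and CDKN1B fell by 0.45 and 0.29. In the stress list TRIB3, ATF3 and DDIT3 fell by 0.50, 0.47 and 0.38 and DDIT4 rose by 0.42. SREBF2 (0.97), NSDHL (0.32) and LSS (-0.33) of cholesterol synthesis, TXNRD1 (0.58) of the redox genes, HK2 (0.47) and NDRG1 (-0.46) of the hypoxia list, NFKBIA (0.39), the apoptosis gene BID (0.46, with another probe at -0.18) and the stromal marker LUM (-0.74) also passed. Leaving out 1 array at a time ended the calls of DDIT3 in 6 of 6 fits, of NOP56, ATF3, DDIT4 and NSDHL in 5, of RRM2, CDC6, CENPF, CDKN1B and LSS in 4 and of CD44 and NFKBIA in 3 (adjusted p up to 0.2). AXIN2 did not pass without ethanol replicate 2 (0.0554), nor LUM without calcitriol replicate 3 (0.0517). With only the 6 LS174T arrays 453 genes passed. With median scaling in place of quantile normalization 504 passed, of which 65.1% were higher, against 46.4% of the 829.

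In SW480 calcitriol raised 109 genes and lowered 229, of which 11 changed at least 2-fold. The largest fitted rise was that of PRSS33, a serine protease that no ethanol array detected (adjusted p = 3.74e-08). It rose at least 3.32-fold, a bound that does not rank it above TPST1 or DENND6B. TPST1, which sulfates protein tyrosines, rose by 1.77 ± 0.12 (adjusted p = 9.62e-07), DENND6B, a regulator of Rab proteins, by 1.76 ± 0.12 (adjusted p = 9.62e-07), LRRN4 by 1.45 ± 0.12 (adjusted p = 9.11e-06) and UGT1A3 by 1.06 ± 0.16 (adjusted p = 0.00329). COL1A1, a collagen gene of the stromal marker list, rose by 0.99 ± 0.15 (adjusted p = 0.00241), the only 1 of 4 measured members to pass, and KLLN and OR1L8 rose by 0.92 and 0.85.

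The falls in SW480 included DKK4, a secreted Wnt antagonist and Wnt target (-1.22 ± 0.12, adjusted p = 8.91e-05), ABCA1, a cholesterol exporter (-1.04 ± 0.21, adjusted p = 0.0154), DLL1, a Notch ligand (-1.03 ± 0.12, adjusted p = 0.000223), and RNF19B, a ubiquitin ligase (-1.01 ± 0.12, adjusted p = 0.000349). IGFBP5, TLE4, a corepressor, KCNS3 and PPP1R3D fell by 0.96, 0.95, 0.94 and 0.92, and TMT1A fell at least 1.79-fold. A second probe of KCNS3 differed by -0.07. Among 14 growth arrest genes CCNG2 fell by 0.96 ± 0.14 (adjusted p = 0.00204) and BTG1 by 0.36 (adjusted p = 0.0433). Of 17 apoptosis regulators the death-promoting BMF and BCL2L11 fell by 0.81 and 0.79. Of 20 interferon response genes IFIT1 and MX2 fell by 0.86 and 0.38 and OAS2 rose by 0.40. In the hypoxia list ANKRD37 fell by 0.59 and ADM rose by 0.28. MYC targets shifted upward as a set, with 18 of 20 differences above 0 and a median of 0.10 (camera adjusted p = 0.018; adjusted p = 0.388 with an estimated correlation), and no member passed with limma (4 at an unadjusted p under 0.05). Leaving out 1 array at a time ended the calls of OAS2 in 6 of 6 fits, of PPP1R3D, BTG1 and ADM in 5, of BCL2L11 in 4 and of OR1L8 and BMF in 3 (adjusted p up to 0.171). Without calcitriol replicate 1 MX2 (0.0522), ABCA1 and ANKRD37 did not pass, nor the last 2 of these without ethanol replicate 2 (adjusted p up to 0.0814). The count of 338 was 178 with array brightness as a covariate, chosen after the data were seen, and 516 without background correction. It fell to 17 with only the 6 SW480 arrays, and to 209, 124, 117 and 215 without ethanol replicates 1 and 2 and calcitriol replicates 1 and 2. Under median scaling 6.56% of 381 genes passing were higher, against 32.2% of the 338.

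**Figure D3:**
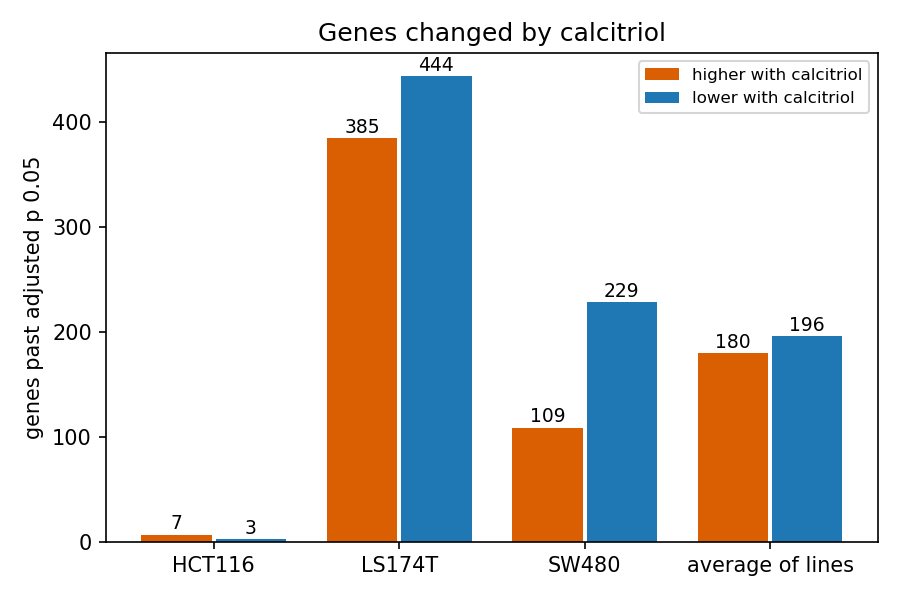
Number of genes past an adjusted p of 0.05 with calcitriol against ethanol, out of 13712 tested, in each line and for the average of the lines, with genes higher in orange and lower in blue. The counts were 7 and 3 in HCT116, 385 and 444 in LS174T, 109 and 229 in SW480, and 180 and 196 for the average.

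Averaged over the lines with equal weight, 180 genes were higher and 196 lower, and all 12 that changed at least 2-fold were higher. After CYP24A1, TRPV6 and CYP3A5, the largest rises with the same sign in every line were those of PRSS33 (1.45 ± 0.07, adjusted p = 3.29e-09), CA2, SULT1C2 (1.10 ± 0.06, adjusted p = 3.23e-08), FOS, SEMA3B, a secreted semaphorin (0.84 ± 0.10, adjusted p = 9.87e-05), GEM (0.84 ± 0.07, adjusted p = 1.39e-06) and SLCO4A1-AS1. The largest falls were those of GPR15LG, GAS7, C1orf116, MTMR11, the oncogene MYCN (-0.57 ± 0.06, adjusted p = 1.1e-05, with another probe at -0.10), TSPOAP1, CEMIP, a hyaluronan-degrading protein (-0.54 ± 0.08, adjusted p = 0.000702), NKD1, CLIC3 and DLX5. The average was carried by LS174T for several of these. GPR15LG and DLX5 were detected on no HCT116 or SW480 array and could not be seen to fall there. MYCN was likewise not detected in HCT116, nor CLIC3 in SW480. Among the rises, FOS differed by 0.07 in HCT116 and 0.03 in SW480. TRPV6 was detected on no HCT116 or SW480 array, PRSS33 on no HCT116 array, and CA2, SULT1C2 and SLCO4A1-AS1 on no SW480 array. Signs there carry no information. No ethanol array detected PRSS33, so its averaged value depends on the background. Of the fixed sets, receptor targets and xenobiotic genes shifted upward (adjusted p = 1.03e-05 and 0.0149 with an estimated correlation). Goblet markers, Wnt targets and the hypoxia list lay lower at the preset correlation (camera adjusted p = 0.0418, 0.0388 and 0.0388) and did not pass otherwise (adjusted p = 0.237 for each with an estimated correlation). IFIT1, TNFAIP3, an inhibitor of NF-kB, and TRIB3 fell by 0.42, 0.48 and 0.20, where the call of TRIB3 ended in 12 of 18 fits without 1 array and that of TNFAIP3 in 2 (adjusted p up to 0.073). No gene of the receptor partner, mesenchymal, or leukocyte and endothelial lists passed in a line or on average with limma (at most 4, 3 and 3 members at an unadjusted p under 0.05). Under median scaling 219 genes passed, 59.8% of them higher, against 47.9% of the 376.

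Responses differed among the lines for 766 genes by the F-test. The pairwise differences passed for 406 genes between LS174T and HCT116, 340 between SW480 and HCT116 and 427 between SW480 and LS174T. The 10 genes with the smallest F-test p were CYP24A1, TRPV6, CYP3A4, CA2, PADI3, FOS, PRR5L, UGT1A1, CYP4F3 and CYP3A5, and all 10 rose most in LS174T. The LS174T response of CYP24A1 exceeded those of HCT116 and SW480 (adjusted p = 4.25e-14 and 2.82e-14), by amounts left open because its LS174T ethanol level was not detected. HCT116 and SW480 already expressed CYP24A1 in ethanol, so the responses started from unlike levels. PADI3 differed by -0.03 in SW480 (adjusted p = 0.933), below its HCT116 response by 1.11 (adjusted p = 0.00688). PRSS33 was detected with calcitriol in SW480 and LS174T, where it rose at least 3.32-fold and at least 2.09-fold, and on no ethanol array and no HCT116 array. Its responses in SW480 and LS174T did not differ past the threshold (adjusted p = 0.141). DKK4 was detected in SW480 and on no array of the other lines, so its responses there could not be seen. The count of 766 was 504 without HCT116 ethanol replicate 3 and 1261 without background correction.

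Calls were shared between lines more often than independent lists would give for some pairs. LS174T and SW480 shared 10 higher genes against 3.06 expected (adjusted p = 0.00391, Fisher's exact test) and 23 lower genes against 7.42 expected (adjusted p = 1.82e-05), and in opposite directions they shared 8 and 1 against 6.43 and 3.53. The lower genes included BCL6, MYCN, CEMIP and TSPOAP1, and the higher ones CDH1, PRSS33 and DENND6B. HCT116 and LS174T shared 4 higher genes, CYP24A1, GEM, PADI3 and SULT1C2, against 0.197 expected (adjusted p = 0.00012, Fisher's exact test). Only CYP24A1 was shared by HCT116 and SW480 (expected 0.0556). Across genes, which are not independent replicates, the log2 changes of LS174T and HCT116 correlated at 0.065, those of SW480 and LS174T at 0.084 and those of HCT116 and SW480 at -0.186.

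Of the genes singled out before the data were examined, VDR, RXRA, MYC and CDKN1A did not pass in any line. VDR, which no HCT116 array detected with calcitriol, differed by 0.16 in LS174T, -0.29 in SW480 and -0.13 in HCT116 (adjusted p from 0.478 to 0.873). RXRA, the heterodimer partner of the receptor, differed by -0.31 in LS174T (adjusted p = 0.0648) and MYC by -0.06 to 0.15. CDKN1A, a cyclin-dependent kinase inhibitor, differed by -0.31 in LS174T (adjusted p = 0.0555), -0.17 in HCT116 and 0.04 in SW480.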

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

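Tests of the receptor level of the lines and of array brightness as a covariate were chosen only after the results on the arrays were seen, and the other tests in this part were set out before their results were seen. The response to calcitriol differed among the lines for 766 genes, with 406 between LS174T and HCT116, 340 between SW480 and HCT116 and 427 between SW480 and LS174T. Permuting the line labels within each treatment gave at most 1 gene in the other splits of 100 drawn. Only the real labels, 1 of 100, reached the 766. Permuted groups mix lines, so where responses differ their spread widens and fewer genes pass. The low counts of the other splits are therefore partly built in, and they do not exclude chance. A chance difference between cultures stays open too, since the replicates may be technical. Of the 139 named genes, 103 differed in response past the threshold, against 766 of all 13712 genes. Many were named for large changes or small p-values in these same data, so a high share was built in. The values below are the largest difference in log2 change between lines, and where a level was not detected they depend on the background and are no bounds, as for CYP24A1 and TRPV6.

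Genes whose largest change was a rise in LS174T differed by these values: CYP24A1 6.91, TRPV6 5.43, CYP3A4 4.69, PADI3 3.98, CYP3A5 3.73, CYP4F3 3.44, CA2 3.31, HSD3B1 3.29, FOS 3.11, PRR5L 2.87, KLK4 2.26, SLCO4A1-AS1 1.91, UGT1A1 1.90 and SULT1C2 1.81. Smaller differences of this kind were those of CLDN2 1.51, KLK6 1.44, CYP4F12 1.35, SEMA3B 1.31, KLK15 1.29, SREBF2 1.19, SERPINB1 1.08, CYP4F2 1.07, CYP2B6 1.03, KLK8 0.98, PHLDA1 0.96, GEM 0.91, BCAS1 0.89 and GADD45A 0.89. The rest of these were EFL1 0.82, CYP3A7 0.79, EGR1 0.74, RRM2 0.71, TXNRD1 0.69, DDIT4 0.68, LRIG1 0.61 and HK2 0.55.

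Genes whose largest change was a negative one in LS174T differed by these values: GPR15LG 2.26, C2CD4A 1.88, SLC3A1 1.80, UGT2B10 1.76, PTGDR 1.76, ODAM 1.73, UGT2B11 1.70, MT4 1.61, SBSPON 1.55, RETNLB 1.55, GAS7 1.47, MYO1A 1.47, C1orf116 1.44 and MTMR11 1.34. Smaller differences among them were those of CLIC3 1.34, SP5 1.32, UGT2B15 1.27, DLX5 1.25, EPHA4 1.24, UGT2B17 1.21, ATOH1 1.01, MYCN 1.00, NKD1 0.95, RGMB 0.92, LUM 0.90, BMP4 0.76, ATF3 0.73 and FCGBP 0.68. The last among them were RNF43 0.57, DSP 0.54, TRIB3 0.54, NDRG1 0.53, TOB1 0.51, CGN 0.47 and SPINK4 0.37. Of these 35 genes 19 were detected on no array of at least 1 other line, where they could not be seen to fall.

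With the largest change in SW480, positive there, were PRSS33 2.29, TPST1 1.82, DENND6B 1.68, UGT1A3 1.66, LRRN4 1.58, KLLN 1.41, COL1A1 1.24, OR1L8 0.99, CDH1 0.83, OAS2 0.58 and ADM 0.47. With a negative one there were RNF19B 1.33, DKK4 1.23, KCNS3 1.12, DLL1 1.11, IGFBP5 1.07, BCL2L11 1.06, CCNG2 1.06, TLE4 1.05, BCL6 1.00, BMF 0.93, TMT1A 0.91, IFIT1 0.88, ANKRD37 0.61 and MX2 0.59. Of these 14 genes 5 were detected on no array of at least 1 other line. With the largest change in HCT116, positive there, were ERV3-1 0.96, COL9A2 0.55 and MMP7 0.52. With a negative one there were POLR1G 1.57, UTP20 1.11, ANGPT1 0.78 and FIRRM 0.67.

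Sets of genes also differed between lines. Canonical receptor targets responded more in LS174T than in HCT116 (camera adjusted p = 8.44e-18; adjusted p = 0.000142 with an estimated correlation) and than in SW480 (camera adjusted p = 2.64e-22; adjusted p = 4.4e-05 with an estimated correlation). Xenobiotic genes did so as well (0.000173 and 0.000247; adjusted p = 0.0353 and 0.0423 with an estimated correlation). Proliferation genes and MYC targets lay higher in the LS174T response than in that of HCT116 (4.85e-06 and 1.57e-05; adjusted p = 0.0353 and 0.0738 with an estimated correlation). They also lay higher in SW480 than in HCT116 (camera adjusted p = 6.97e-05 for each; adjusted p = 0.167 and 0.19 with an estimated correlation). Goblet markers lay lower in LS174T than in HCT116 and SW480 (0.0259 and 0.00856; adjusted p = 0.177 and 0.128 with an estimated correlation), where only 4 and 3 of the 12 were detected and the rest could not be seen to fall. Wnt targets lay lower in LS174T than in HCT116 (0.0188; adjusted p = 0.119 with an estimated correlation). ERK genes lay higher in LS174T than in SW480 (0.00577; adjusted p = 0.0423 with an estimated correlation). Apoptosis regulators lay higher in LS174T than in HCT116 and SW480 (0.0437 and 0.0267; adjusted p = 0.092 and 0.065 with an estimated correlation).

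Probes without a listed gene, which the comparisons above do not use, also responded. Of 7037 such probes 130 passed in LS174T, 77 of them higher, 38 in SW480, 13 of them higher, and 46 on average, 31 of them higher. None passed in HCT116 with limma (574 at an unadjusted p under 0.05).

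LS174T had 829 genes past the threshold and HCT116 had 10. A smaller spread between LS174T replicates could not lower the SE there, since all groups shared an estimate of the spread. In fits to only the line's own arrays, 453 genes passed in LS174T and 3 in HCT116. The median residual SD was 0.14 in LS174T and 0.144 in HCT116, a ratio of 0.968. Genes silent in HCT116 were argued against as the whole cause. Among 520 LS174T genes detected on all arrays, the median change in the LS174T direction was 0.468 in LS174T. It was 0.015 in HCT116, a ratio of 0.033. LS174T also had the highest VDR level in ethanol, and the level of the receptor may set the size of the response. The order of the 3 lines by VDR level was also their order by genes past the threshold, with 338 in SW480. The receptor targets as a set did not follow it. Their shift held with an estimated correlation in HCT116, where VDR was lowest, and did not in SW480. With 3 lines, an effect of the receptor level cannot be told apart from any other difference between them.

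Across genes the changes in HCT116 and SW480 ran in opposite directions, with a correlation of -0.186. Joint splits of the arrays reached this size in 3 of 100, the real one included, with a highest other value of 0.211. The share lay under 0.05 but was not adjusted for picking this pair out of all pairs of lines, so chance stays open. Array brightness also ran in opposite directions, with calcitriol minus ethanol at 0.086 log2 units in HCT116 and -0.12 in SW480 (0.089 in LS174T). With brightness as a covariate the correlation was -0.192. Error in a gene's fitted brightness slope enters the HCT116 and SW480 changes with opposite signs and itself adds a negative correlation. The covariate therefore cannot decide, and brightness stays open. The SW480 arrays numbered 1, 2 and 3 gave -0.152, -0.182 and -0.044, but the numbers do not pair the arrays, so these values decide nothing. Growth state stays open: proliferation genes had a mean change of -0.16 in HCT116 and 0.06 in SW480, and MYC targets -0.17 and 0.14, while the partial correlation of -0.179 rests on loadings that ran against these shifts (0.083 and -0.091).

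For the counts within a line the 6 arrays have only 10 splits, too few for a share under 0.05, and 1 of 10 reached the real count in each line. The real counts and the highest of the other splits were 10 and 1 in HCT116, 829 and 8 in LS174T and 338 and 1 in SW480. For the average, 1 of 100 splits within lines, the real one, reached the 376 (highest other 158). For the lines in ethanol 1 of 100 splits of the 9 ethanol arrays, the real one, reached the 10834 that they gave (highest other 3776). The other splits mix lines, or treated with untreated arrays, so where these differ the spread widens and fewer genes pass. A split drawn for the average may also keep the real grouping of a line. The shares therefore do not exclude chance for either count. Chance differences between cultures stay open too, since the replicates may be technical.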

How the results depend on the processing

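Array brightness as a covariate was chosen only after the data were seen, and the other alternatives before. CDH1 kept its direction under every alternative in every line and its side of the threshold in all but 1, HCT116 without background correction (0.368, adjusted p = 0.0252, in a range of 0.0252 to 0.461). None of the 247 results for single named genes changed sign where it or its alternative passed the threshold. Of their 5784 alternative values 5145 kept their side of the threshold, 551 fell short of the threshold and 88 newly passed it. Changes of sign between values that both fell short were not counted apart from the 5145. Of 149 named results past the threshold, CDH1 included, 0 changed sign under any scaling.

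Counts that moved by more than 1.5 times are given here, and the cause was not tested unless stated. Without background correction HCT116 had 23 genes, SW480 516 and the differing responses 1261. With trend and robust settings HCT116 had 24. Under median scaling LS174T had 504 and the average 219. With the replicate number as a block HCT116 had 2, LS174T 525, SW480 72, the average 189 and the differing responses 230. The numbers do not pair the samples: 0 of 9 ethanol arrays matched the calcitriol array of their own number best, and same-number correlations lay between -0.09 and 0.0012. A log2 change of at least 1 left 4, 118, 11, 12, 188 and 5664 genes in HCT116, LS174T, SW480, the average, the differing responses and the lines in ethanol, a stricter demand by construction. With only the arrays of the line, which leaves fewer samples to estimate the spread, HCT116 had 3, LS174T 453 and SW480 17. With brightness as a covariate HCT116 had 5 and SW480 178. With every probe on its own, which tests more features, 17933 differed among the lines in ethanol. The deposited log2 values gave 10, 829, 338 and 373 in the lines and the average, of which 10, 829, 337 and 373 were shared with the counts reported.

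Without background correction HCT116 and LS174T shared 10 higher and 2 lower genes, HCT116 and SW480 shared 3 higher, and LS174T and SW480 shared 17 higher and 38 lower. The correlation of HCT116 and SW480 was then -0.258. With trend and robust settings the shared counts were 10 and 1, 2, and 16 and 39. Of 84 list tests 16 passed at the preset correlation and 6 with an estimated correlation.

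Leaving out each array in turn gave 3 to 13 genes in HCT116, 555 to 862 in LS174T, 117 to 289 in SW480, 297 to 372 for the average, 504 to 806 for the differing responses and 10644 to 10943 for the lines in ethanol. The HCT116 count was 4 without ethanol replicate 3, and 5, 3 and 6 without calcitriol replicates 1, 2 and 3. The SW480 count was 209 and 124 without ethanol replicates 1 and 2, and 117 and 215 without calcitriol replicates 1 and 2. The differing responses were 504 without HCT116 ethanol replicate 3. The BeadChip as a block was not run, since the files do not name the chips, and CDH1 had no other probe to try. Signal limits what is seen, as between 40.8% and 44.4% of probes were detected per array.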

Other observations

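The gene families and neighbouring genes below, the genes named for them, and all tests in this part were chosen only after the LS174T result was seen. Several gene families held more genes past the threshold in one direction in LS174T than their size would give. Of 29 cytochrome P450 genes 8 rose (adjusted p = 0.000427, one-sided Fisher's exact test over families), among them CYP4F12 by 1.28 ± 0.11 and CYP4F2 by 0.99 ± 0.13. Of 10 kallikreins 5 rose (adjusted p = 0.000887): KLK4 by 2.09 ± 0.13, KLK6 by 1.64, KLK15 by 1.03, KLK8 by 0.97 and KLK7 by 0.97. Of 5 HES genes, transcriptional repressors that include Notch targets, 4 were lower (adjusted p = 0.00246): HES5 fell by 1.01 ± 0.17, HES2 fell by 0.59, HES1 fell by 0.48 and HES6 fell by 0.38. Of 12 genes with the symbol root UGT 5 were lower (adjusted p = 0.00531), among them UGT2B17, which fell by 1.23 ± 0.15, and UGT2A3, not detected with calcitriol, while 2 others of the 12, UGT1A1 among them, rose (adjusted p = 1). All named members kept their sign under the scalings tried, and similar sequences mean that probes of a family are not independent.

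Several of these genes are neighbours, as are BCAS1 (0.83), CYP24A1 and PFDN4 (0.92), which all rose in LS174T. Among 13675 adjacent pairs of tested genes, 80 were past the threshold in one direction, against a mean of 25.2 and a highest of 43 in 10000 shuffles of the calls (permutation p = 1e-04, the smallest the shuffles can give). Families of similar sequence were argued against as the whole cause, since 62 pairs without a shared symbol root were counted against a mean of 23.6 and a highest of 41. Overlapping genes were argued against likewise, since 72 pairs with separate annotated spans were counted against a mean of 22.6 and a highest of 41. Neighbouring genes may therefore share regulation by calcitriol in LS174T, a hypothesis that was found and tested on the same data and that these arrays cannot take further.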
